A study of Danio rerio with 32 samples.

How the data were processed

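The series measured gene expression and DNA methylation in liver and brain of adult zebrafish kept in water with PCB126 or with the solvent DMSO for 24 h and then in clean water for 7 days. PCB126 is a dioxin-like polychlorinated biphenyl that activates the aryl hydrocarbon receptor (AHR), a ligand-activated transcription factor. RNA and DNA came from the same isolation, per the labels' protocols, and each of the 8 groups (tissue, treatment and assay) held 4 individual fish. The 16 RNA libraries were made with a total RNA kit. The 16 methylation libraries were made by enhanced reduced representation bisulfite sequencing, in which DNA is digested with TaqaI and MspI before bisulfite treatment, per the labels' protocols. Groups and replicate numbers were taken from the sample labels. The sex of the fish and the dose of PCB126 are not given in the sources used here.

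The deposited RNA files hold whole-number counts of reads per Ensembl gene ID with no normalization, in the layout of HTSeq. STAR and the zebrafish assembly GRCz10 are named for the series, per the submitters' processing notes. The versions, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart, and values of close paralogs are uncertain where the authors' counting could split or drop their reads. The closing counter lines name no gene and were kept out of library sizes and tests. Of all reads on these lines and in genes, 2.05 to 6.85% in liver and 17.1 to 24.4% in brain lay outside genes, 0.893 to 6.49% were ambiguous and 14.0 to 53.9% mapped to more than 1 place. Between 16888204 and 26133136 reads per library lay in genes. No pair of libraries of a group matched within sampling noise (lowest chi-square per degree of freedom 15.2).

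The deposited methylation files give, per the file headers, the chromosome position, strand, coverage and the percent of reads called C (methylated) or T (unmethylated) for single cytosines of CpG sites, on 1 strand each. Bismark and methylKit are named for these files, per the submitters' processing notes, again with GRCz10 and with no versions. The lowest coverage listed was 10 in each of the 16 libraries, and coverage times percent gave whole read counts for all cytosines, so methylated and unmethylated counts were taken back from the authors' values. A library listed 587981 to 2128731 cytosines with a median coverage of 14 to 29 reads. The 8 liver libraries shared 453831 cytosines and the 8 brain libraries 360821. Positions are in GRCz10 as the files give them. An annotation of that assembly was not used here, so windows are given by position only, and the planned comparison of changed genes with changed windows was not run.

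Gene symbols came from a table of gene IDs and symbols. Of 32266 IDs, 26433 had a symbol. A symbol that several IDs share is followed by the last digits of the ID, and CYP1A1 is the cyp1a gene. The 38 gene lists (pathways, and markers of cell types that a liver or brain sample could hold) had 888 entries, of which 816 matched an ID. A list of skeletal muscle markers was added after the data were seen.

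Expression was tested in each tissue with edgeR 4.0.16 in R 4.3.3: TMM scaling, a filter on low counts by group, a robust quasi-likelihood fit and Benjamini-Hochberg adjustment, with genes called at an adjusted p under 0.05. The difference of the effects in the 2 tissues was tested as an interaction in all 16 libraries. The SE given with a log2 fold change was taken back from the test, as the absolute log2 fold change over the square root of F. It was not estimated by the fit itself and is approximate. CPM (counts scaled by library size) of named genes use TMM-scaled library sizes, while marker levels and shares of reads use plain totals. For genes with few reads in a group, the ratio of summed reads has an exact 95% interval that covers counting error only. Gene lists with at least 5 tested members were tested with camera of limma 3.58.1, with a preset correlation of 0.01 between genes, and beside it with an estimated correlation and with fry. Camera's preset correlation treats genes of a list as nearly independent.

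Methylated and unmethylated reads were summed in windows of 1000 bp over CpG cytosines with a coverage of at least 10 and under the library's 99.9th percentile. Windows with reads in all 8 libraries were tested with a quasi-binomial logistic model whose dispersion between fish was moderated across windows. A window was called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 10 percentage points. A library's window level rests on its own listed cytosines, which can differ between libraries. So the windows were tested again over cytosines present in all 8 libraries, a choice made after the data were seen. Mean levels over shared cytosines were compared with exact two-sided permutation tests, for which 4 against 4 fish give a smallest p of 0.0286.

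The designs, gene lists, naming rule and most alternatives were fixed before the data were examined. The alternatives cover scaling, filters, tools, window and coverage choices, blocks and leaving out each fish. Named were, per tissue, the 10 higher and the 10 lower called genes with the largest fold change. They had to have at least 1 CPM in a group, no overlap between the groups and a symbol not based on a clone. Where fewer than 5 passed in a direction, the 5 with the smallest p were named as well. All AHR target genes, up to 4 called members of each other list, 5 genes per direction of the interaction and up to 5 called windows per direction without overlap were named too. Of these genes, 2 are not reported here.

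Both tests were checked on simulated data with 200 changed genes or windows, 100 for each size. Gene counts were drawn from the real means, depths and spreads. Windows were drawn from the real levels and depths, but with the same preset spread between libraries in all windows. Changed windows were taken from those of intermediate level. The rates for windows therefore hold for that preset spread and need not hold for the real one. In liver, with 15810 genes, 0% of genes changed 2-fold and 16% of those changed 4-fold were called, with 0 unchanged genes. In brain, with 20096 genes, 25% and 70% were called, and 6 unchanged genes made up 5.94% of the calls. The window test called 0% of windows changed by 20 points and 17% of those changed by 30 points in liver, and 1% and 3% in brain, with 0 unchanged windows in either tissue.

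Whether equal replicate numbers in liver and brain mark 1 fish was read from the deviations of each library from its group mean. Over 289859 cytosines the correlation for equal numbers was 0.310 to 0.386 in DMSO and 0.259 to 0.306 in PCB126 fish, and at most -0.0446 for unequal numbers. The numbers were therefore taken to pair the 2 tissues of a fish, and a fit with the fish as a block is given where it moves a result. DESeq2 1.42.0 served as an alternative test, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the remaining steps.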

Results

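Liver and brain of adult zebrafish were compared between fish exposed to PCB126 and fish exposed to the solvent DMSO, 7 days after a 24 h exposure, with 4 fish per group, by RNA sequencing and by reduced representation bisulfite sequencing. Reads in genes ranged from 17471652 to 26133136 per liver library and from 16888204 to 22063765 per brain library. For methylation, the reads summed over listed CpG cytosines ranged from 14886314 to 91125645 in liver. In brain they ranged from 30325684 to 68844617 in the 4 DMSO libraries and from 9768347 to 20847883 in the 4 PCB126 libraries, so the brain groups differed in depth without overlap.

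The levels of tissue and exposure markers matched the sample labels. The liver genes fabp10a, a fatty acid binding protein of hepatocytes, and tfa, transferrin, lay at 2325 to 22504 CPM and 15133 to 76457 CPM in the 8 liver libraries. The neuronal gene elavl3 lay at 99.0 to 366 CPM in the 8 brain libraries and at most at 0.0507 CPM in liver, and the astroglial gene gfap lay at 37.5 to 157 CPM in brain and at most at 0.257 CPM in liver. In 1 brain library, PCB126 replicate 1, fabp10a reached 104 CPM and tfa 385 CPM. The AHR target cyp1a, a cytochrome P450 enzyme that metabolises aromatic compounds, lay at 355 to 693 CPM in DMSO livers and 21839 to 33844 CPM in PCB126 livers. In brain the ranges were 3.44 to 7.05 CPM and 1409 to 2288 CPM.

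**Figure D1:**
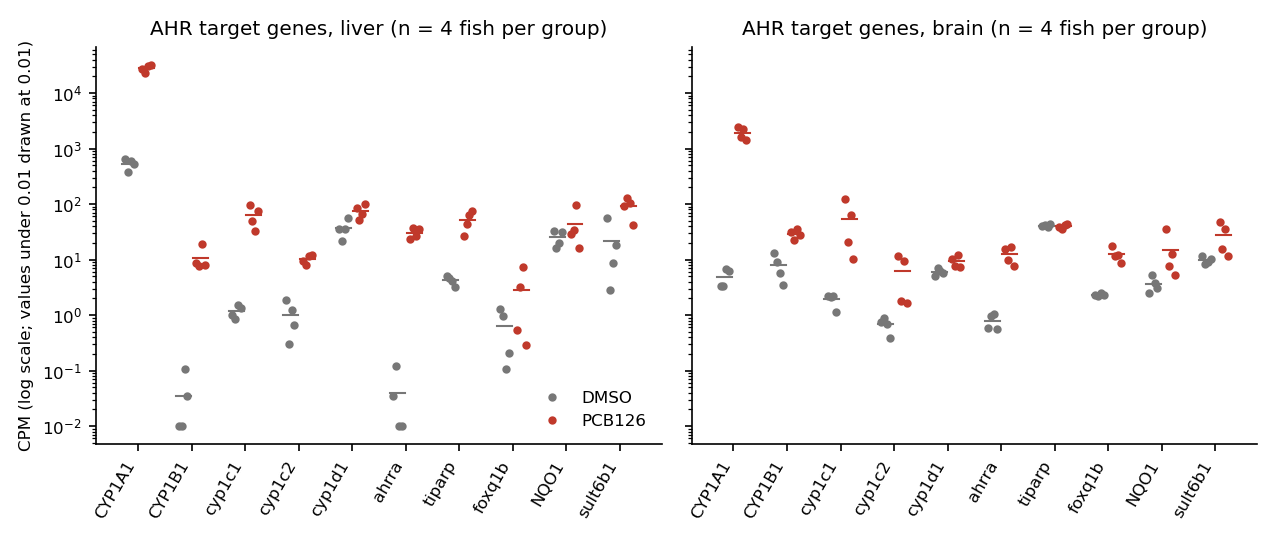
Normalised read counts (CPM, log axis) of 10 AHR target genes in liver and brain, with 1 point per fish and a line at each group mean. CYP1A1 lay at 538 CPM in DMSO and 28256 CPM in PCB126 livers on average, and tiparp at 40.8 CPM in DMSO and 39.8 CPM in PCB126 brains.

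The first comparison asked which genes differ in liver after PCB126. Known targets of the AHR rose. CYP1A1 (ENSDARG00000098315) rose from 538 ± 115 to 28256 ± 3851 CPM (SD, n = 4), a log2 fold change of 5.72 (SE 0.45), and cyp1c1 (ENSDARG00000101195), a P450 of the same family, rose from 1.17 ± 0.298 to 63.2 ± 27.5 CPM. The AHR repressor ahrra (ENSDARG00000099702) rose from 3 reads in the 4 DMSO livers to 2734 reads in the 4 PCB126 livers, a ratio of 934 after scaling for depth (95% interval 319 to 4533). CYP1B1 (ENSDARG00000068934) rose from 4 to 1009 reads, a ratio of 259 (101 to 951), and tiparp (ENSDARG00000061841), which encodes a polymerase that represses the AHR, rose from 4.26 ± 0.787 to 52.2 ± 21.0 CPM. Outside the naming rule, 2 further genes passed, ENSDARG00000097714 and ENSDARG00000100141, which are named here after their values were seen. The former rose by 4.56 on the log2 scale, and the latter from 1 read in the DMSO to 100 reads in the PCB126 livers, a ratio of 102.5 (95% interval 18 to 4089).

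Of 15810 genes, 7 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment in liver, 7 higher and 0 lower with PCB126. At an unadjusted p under 0.05 there were 1417 genes, DESeq2 called 364 (168 higher, 196 lower) and voom 150. In 5.25% of genes the values of the groups did not overlap, where chance gives 2.86%. The adjusted p of the named genes was 0.00266 for ahrra and cyp1c1, 0.00284 for CYP1A1, 0.00957 for CYP1B1 and 0.00994 for tiparp by edgeR. The count was 50 without DMSO replicate 2, 4 without DMSO replicate 3, 2 without DMSO replicate 4 and 3 without PCB126 replicate 3. Of the named genes, ahrra and cyp1c1 passed in all 8 leave-outs. CYP1A1 did not without DMSO replicate 4 (adjusted p 0.0770), CYP1B1 not without DMSO replicate 4 or PCB126 replicate 3 (0.0953, 0.0569), and tiparp not without DMSO replicate 3, DMSO replicate 4 or PCB126 replicate 3 (0.111, 0.0953, 0.0587).

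No gene was lower past the test in liver, and the 5 with the smallest p are given with their values. The chemokine gene ccl39.2 lay at 837 ± 373 CPM in DMSO and 122 ± 33.6 CPM in PCB126 livers (n = 4; edgeR adjusted p 0.106). The clock gene bmal2 lay at 5.53 ± 1.4 and 1.59 ± 0.361 CPM (0.115). The extracellular matrix gene emilin1b lay at 33.0 ± 3.32 and 12.4 ± 1.91 CPM (0.0763). CCDC28B had 403 reads in DMSO and 8 in PCB126 livers (0.0607), and the chemokine receptor gene ccr11.1 had 147 and 7 (0.106).

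As a list, the AHR target genes rose in liver. Of 10 tested, 5 were higher (8 when adjusted over the list alone), with a median log2 fold change of 3.47 and a camera adjusted p of 6.47e-22, and of 0.00429 with an estimated correlation. The members not past the test had log2 fold changes of 3.33 (cyp1c2), 2.19 (foxq1b), 2.08 (sult6b1), 1.02 (cyp1d1) and 0.80 (NQO1). Of 33 lists, 16 were called by camera, 8 higher and 8 lower, and with an estimated correlation 1, the AHR targets.

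The other 15 lists called in liver held no gene past the test on all genes, and they are described by their medians. Antioxidant and glutathione genes of the oxidative stress list had a median log2 fold change of 0.71 over 26 genes (10 higher when adjusted over the list alone; camera adjusted p 9.11e-07; adjusted p = 0.384 with an estimated correlation). Conjugation and transport genes had a median of 0.59 over 22 genes (2 higher over the list alone; adjusted p = 0.384 with an estimated correlation; 0.120 without DMSO replicate 2). AHR receptors and partners had a median of 0.39 over 8 genes (2 higher over the list alone; adjusted p = 0.294 with an estimated correlation; 0.0805 without DMSO replicate 2, 0.0552 without PCB126 replicate 4). Heat shock and folding genes had a median of 0.38 over 34 genes (adjusted p = 0.457 with an estimated correlation; 0.176 without DMSO replicate 2, 0.104 without DMSO replicate 4, 0.351 without PCB126 replicate 3).

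Several lists of liver metabolism were lower by camera. The median was -0.58 over 23 genes of bile acids and lipoproteins and -0.35 over 26 of fatty acid oxidation (1 lower when adjusted over the list alone). It was -0.43 over 18 genes of fatty acid and triglyceride synthesis (2 lower over the list alone) and -0.48 over 22 of thyroid and steroid signalling (5 lower over the list alone). With an estimated correlation none held (adjusted p = 0.384, and 0.150 for fatty acid synthesis). Vitellogenin took 5.01% or more of reads in 3 of the 4 PCB126 livers and in 1 of the 4 DMSO livers. With its level as a covariate, chosen after the data were seen, these 4 lists stayed called, with a median of -0.20 for fatty acid oxidation. Of the 16 called lists, 2 then lost their call, the markers of intestine (camera adjusted p 0.155, median -1.82) and erythrocytes (0.0719, median -0.60).

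Markers of other cell types also differed between livers. Exocrine pancreas markers, digestive enzymes of a gland that lies within and along the liver of many fish, had a median of 1.77 over 28 genes (1 higher when adjusted over the list alone; camera adjusted p 1.4e-11; adjusted p = 0.384 with an estimated correlation). Their share of reads was 1.4% in PCB126 replicate 1 and 0.0781 to 0.724% in the other 7, and without that library the median was 0.64. Neutrophil markers had a median of 1.48 over 7 genes (3 higher over the list alone; adjusted p = 0.200 with an estimated correlation). Intestine markers had a median of -3.46 over 10 genes (5 lower over the list alone; adjusted p = 0.606 with an estimated correlation; 0.150 without DMSO replicate 1). Endothelial and erythrocyte markers had medians of -0.52 over 14 and -0.88 over 7 genes (adjusted p = 0.384 with an estimated correlation). Fibroblast markers had a median of 0.32 over 16 genes (adjusted p = 0.707 with an estimated correlation; 0.749 without DMSO replicate 2, 0.0773 without PCB126 replicate 1). Neuron markers had a median of -0.64 over 6 (2 lower over the list alone; adjusted p = 0.384 with an estimated correlation; 0.218 without DMSO replicate 2, 0.0764 without PCB126 replicate 3, 0.0745 without PCB126 replicate 4).

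**Figure D2:**
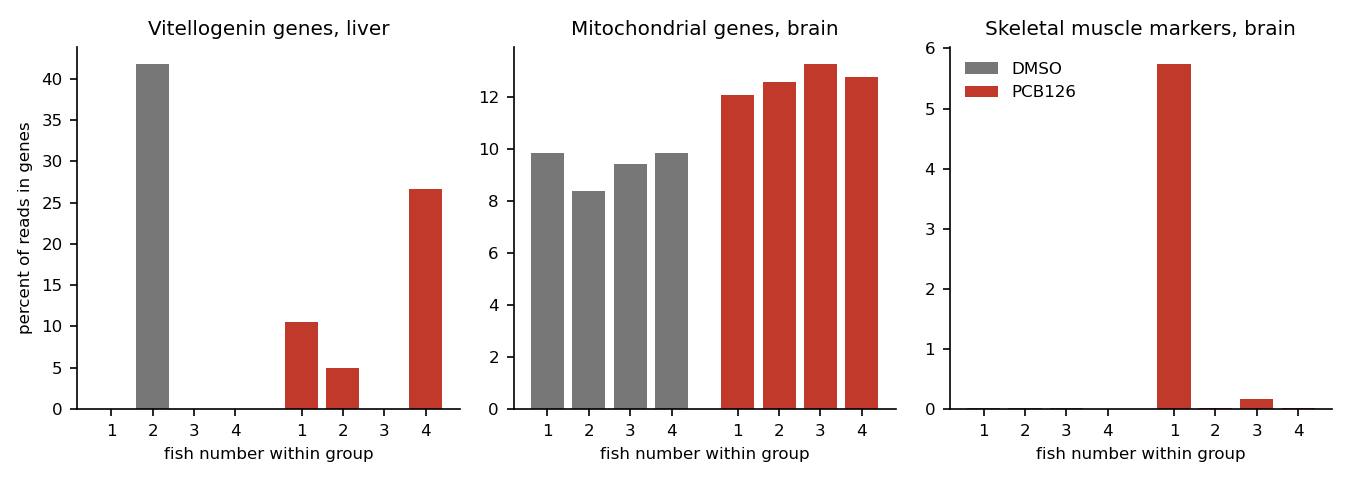
Share of reads in genes (percent, bars from 0, 1 bar per library) of vitellogenin genes in the 8 livers, of mitochondrial genes in the 8 brains and of skeletal muscle markers in the 8 brains. Vitellogenin reached 41.7% in DMSO replicate 2, mitochondrial genes lay at 8.40 to 9.86% in DMSO and 12.1 to 13.3% in PCB126 brains, and muscle markers reached 5.74% in PCB126 replicate 1.

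Livers of a group differed in vitellogenin, the egg yolk precursor that egg-laying females make in liver under estrogen. Vitellogenin genes took 41.7% of reads in genes in DMSO replicate 2 and 0.000951 to 0.0202% in the other 3 DMSO livers. In PCB126 livers they took 10.5%, 5.01%, 0.00162% and 26.6% in replicates 1 to 4. Reads that mapped to more than 1 place took 53.9% in DMSO replicate 2, 36.8%, 30% and 47.8% in PCB126 replicates 1, 2 and 4, and 16.4 to 20.6% in the other 4. With the vitellogenin level as a covariate, chosen after the data were seen, the liver test called 32 genes.

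The second comparison asked the same of the brain. AHR targets rose there as well. CYP1A1 rose from 4.86 ± 1.77 to 1933 ± 488 CPM (SD, n = 4), a log2 fold change of 8.64 (SE 0.39), and cyp1c1 from 1.91 ± 0.505 to 55.0 ± 52.4 CPM. The forkhead gene FOXQ1 (ENSDARG00000030896) rose from 0.356 ± 0.244 to 8.08 ± 1.52 CPM, ahrra from 0.782 ± 0.247 to 12.5 ± 4.38 CPM and CYP1B1 from 7.91 ± 4.23 to 29.5 ± 5.77 CPM. Log2 fold changes were 3.14 for cyp1c2, 2.45 for foxq1b, 2.04 for the quinone reductase NQO1 and 1.49 for the sulfotransferase sult6b1. In all, 9 of 11 targets were higher (10 when adjusted over the list alone), with a camera adjusted p of 2.03e-07 for the list (adjusted p = 0.810 with an estimated correlation; fry 0.00177). Not past the test were cyp1d1 (0.63, edgeR adjusted p 0.0722) and tiparp, at 40.8 ± 2.26 and 39.8 ± 3.23 CPM.

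Among the largest increases in brain beside CYP1A1 and cyp1c1 was that of the chemokine gene cxcl19 (10 reads in DMSO, 409 in PCB126 brains; ratio 44.9, 95% interval 24.2 to 94.3). Further ones by the naming rule were ADM_69027 (adrenomedullin, log2 fold change 5.66, SE 1.43), UROC1 (a liver enzyme of histidine breakdown, 5.42, SE 1.4), the trypsin prss59.2 (4.94, SE 1.37), tspan34b (4.67, SE 1.08), TIMP4_02617 (a protease inhibitor, 4.59, SE 1.18) and icn2 (4.54, SE 1.17). Their highest value lay in PCB126 replicate 1, such as 36.6 CPM of UROC1 and 44.8 CPM of prss59.2 against 0.743 to 5.14 and 1.0 to 2.5 CPM in the other 3. In that library skeletal muscle markers, added after the data were seen, took 5.74% of reads, with ckmb at 14360 CPM, against 0.168% in PCB126 replicate 3 and at most 0.0234% in the other 6 brains.

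The largest decreases in brain were those of igfn1.2, a muscle-type immunoglobulin and fibronectin domain gene (218 reads in DMSO, 2 in PCB126 brains), OCIAD2 (-4.72, SE 0.69) and MTHFD1L, an enzyme of mitochondrial folate metabolism (-2.37, SE 0.56). For these 3 the highest DMSO value lay in replicate 1. The myostatin gene mstna fell from 10.2 ± 2.5 to 2.15 ± 1.51 CPM (n = 4), csf1a, a growth factor of macrophages, from 3.80 ± 1.3 to 0.965 ± 0.633 CPM, and nes (nestin, an intermediate filament of neural progenitors) from 30.8 ± 16.2 to 10.2 ± 2.40 CPM. The rest were prrt4a (-1.62), loxl5b (-1.79), chadlb (-1.51) and ANTXR1_25672 (-1.45).

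**Figure D3:**
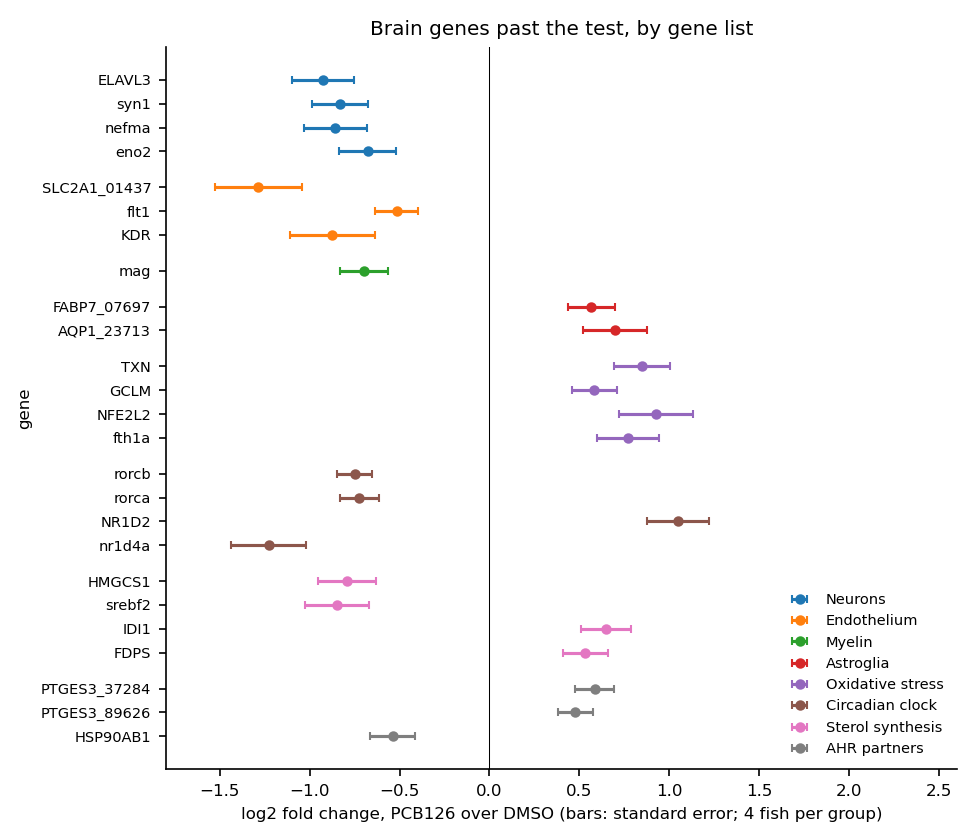
Log2 fold change (PCB126 against DMSO, points, with SE as bars) of brain genes past the test from 8 gene lists, grouped by list. Among the neuron markers ELAVL3 fell by 0.92 and syn1 by 0.83, while TXN of the oxidative stress list rose by 0.85.

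Neuron markers fell in brain, 6 of 17 past the test (10 when adjusted over the list alone) with a median log2 fold change of -0.54. Their share of reads was 0.975 to 1.08% in DMSO brains and 0.575%, 0.976%, 0.890% and 0.936% in PCB126 replicates 1 to 4. PCB126 replicate 1, the lowest, is the library with 5.74% muscle reads, and without it the median was -0.40 (camera adjusted p 0.00201). With all fish camera gave this list an adjusted p of 4.66e-04 (adjusted p = 0.810 with an estimated correlation). The share of mitochondrial reads also moved with the groups, 8.40 to 9.86% in DMSO and 12.1 to 13.3% in PCB126 brains. ELAVL3, an RNA-binding protein of neurons, fell from 327 ± 15.5 to 172 ± 40.3 CPM (SD, n = 4), the synaptic vesicle gene syn1 from 513 ± 44.3 to 288 ± 53.3 CPM, the neurofilament gene nefma from 264 ± 32.8 to 146 ± 32.4 CPM and eno2 from 432 ± 35.3 to 270 ± 51.0 CPM. The vesicular glutamate transporter SLC17A7_16480 fell by 0.96 on the log2 scale. Oxidative stress genes rose, 8 of 25 past the test (14 when adjusted over the list alone) with a median of 0.58. Among them were thioredoxin TXN (0.85), NFE2L2 (0.93), the transcription factor of the antioxidant response, GCLM (0.58), an enzyme of glutathione synthesis, and the ferritin gene fth1a (0.77). Of 19 conjugation and transport genes, 4 rose and 1 fell (9 and 1 when adjusted over the list alone), with gains of 1.4 in the sulfotransferase sult1st1, 1.26 in gsta.1 and 0.95 in gstp1.2, and a loss in the efflux transporter ABCB4 (-0.88). Camera's adjusted p was 0.00281 for oxidative stress and 0.0215 for conjugation and transport (adjusted p = 0.810 with an estimated correlation for both). Without both PCB126 replicates 1 and 3, the 2 brains highest in muscle reads, a choice made after the data were seen, the conjugation list was not called (adjusted p 0.161, median 0.25), while camera gave 0.00621 for neurons (median -0.33) and 0.0419 for oxidative stress (median 0.36).

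Single markers of immune cells and connective tissue rose in PCB126 brains. Of 8 neutrophil markers 2 rose (8 when adjusted over the list alone), the metalloprotease npsn by 4.09 and the cytokine receptor il6r by 2.43 on the log2 scale. Of 13 lymphocyte markers cd8b rose (2.55), and of 17 fibroblast markers TAGLN_33466 (1.46), both with 0 when adjusted over the list alone. Of 18 microglia and macrophage markers and 21 interferon genes 0 passed the test, over all genes or over the list alone, and these lists were not called (camera adjusted p 0.0903 and 0.541). The 30 proliferation genes had a median of 1.23, with 0 past the test over all genes or over the list alone, and fry gave this list an adjusted p of 0.360. Camera's adjusted p was 0.0170 for neutrophils, 0.0359 for lymphocytes and fibroblasts and 0.00571 for proliferation (adjusted p = 0.810 with an estimated correlation for all 4). Without PCB126 replicate 1, the library with muscle reads, it was 0.0592 for neutrophils, 0.204 for lymphocytes, 0.185 for fibroblasts and 0.148 for proliferation, and without both PCB126 replicates 1 and 3 it was 0.310, 0.650, 0.931 and 0.310. For lymphocytes it was also 0.0558 without DMSO replicate 1, 0.0812 without DMSO replicate 4 and 0.0667 without PCB126 replicate 3, and for fibroblasts 0.0746 and 0.0900 without the latter 2. Of 38 lists, 8 were called by camera, 7 higher and 1 lower, and 0 with an estimated correlation (1 by fry). The count was 13 without DMSO replicate 2, 13 without DMSO replicate 3 and 14 without PCB126 replicate 2.

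Other lists were not called, but held genes past the test in brain. Their counts stand beside 2958 of 20096 over all brain genes, 1462 higher and 1496 lower. Of 34 circadian clock genes 4 rose and 9 fell (6 and 12 when adjusted over the list alone). The nuclear receptor genes rorcb and rorca, which drive clock transcription, fell from 177 ± 15.6 to 105 ± 3.30 CPM and from 52.4 ± 4.99 to 31.7 ± 2.47 CPM (n = 4), nr1d4a fell by 1.23 on the log2 scale and NR1D2 rose by 1.05. In sterol synthesis, the regulator srebf2 (-0.85) and HMGCS1 (-0.79) fell while IDI1 (0.65) and FDPS (0.53) rose (2 of 25 higher and 3 lower; 4 and 8 over the list alone). The lipogenic genes SREBF1 (-0.82) and SCD (-1.18) fell and DGAT1_54914 (0.44) rose. Of the partners of the AHR, the co-chaperones PTGES3_37284 (0.59) and PTGES3_89626 (0.48) rose and HSP90AB1 (-0.54) fell (3 of 9 higher, 1 lower; 4 and 2 over the list alone). Camera's adjusted p was 0.195 for the clock, 0.154 for sterols, 0.424 for fatty acid synthesis and 0.541 for AHR partners.

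Markers of the blood vessel wall fell in 3 of 15 cases in brain (3 over the list alone), with the glucose transporter SLC2A1_01437 (-1.29) and the receptors KDR (-0.87) and flt1 (-0.52). The myelin gene mag fell (-0.70, 1 of 10), and the radial glia genes FABP7_07697 (0.57) and AQP1_23713 (0.70) rose (2 of 14). In the list of DNA methylation and one-carbon metabolism, 1 of 38 rose and 4 fell (1 and 4 over the list alone). There the demethylation enzyme gene tet3 (-0.59), MAT2A_40334 (-0.46), which makes the methyl donor, and AHCYL1 (-0.51) fell, and GADD45A_04571 rose (1.05). The chaperones HSPE1 (0.73), CALR (0.53) and SERPINH1_75954 (1.18) rose and HSPA4_18989 fell (-0.47). Camera's adjusted p lay at 0.235 or above for these 5 lists. Over all brain genes 2958 of 20096 passed the test, so called members were about as frequent here as among genes at large.

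In brain 2958 of 20096 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1462 higher and 1496 lower, with a median absolute log2 fold change of 0.67 and 489 genes at 1 or more. The groups did not overlap in 26.2% of genes, where chance gives 2.86%. Many of these calls lay close under the threshold, and the count was 5 without DMSO replicate 1, 3 without DMSO replicate 2, 7 without DMSO replicate 3, 840 without DMSO replicate 4, 4 without PCB126 replicate 2, 1494 without PCB126 replicate 3 and 4464 without PCB126 replicate 4. Of the 92 brain genes that the naming rule gave as past the test, 2 passed without DMSO replicate 1, 2, 3 or PCB126 replicate 2 each, 33 without DMSO replicate 4, 45 without PCB126 replicate 3, 79 without PCB126 replicate 1 and 86 without PCB126 replicate 4. CYP1A1 passed in all 8 leave-outs (edgeR adjusted p 1.09e-04 with all fish). At an unadjusted p under 0.05 there were 7483 genes with all fish. The leave-outs gave from 5700 (without DMSO replicate 1) to 8398 (without PCB126 replicate 4). Fitted with all 16 libraries, the brain comparison called 10 genes. The brain groups also differed in their share of mitochondrial reads, 9.38 ± 0.684% in DMSO and 12.7 ± 0.484% in PCB126 fish (n = 4, exact permutation p = 0.0286, the smallest possible). Without mitochondrial genes the count was 2958 too (1529 higher, 1429 lower), with 2884 of these also called before. Leaving these genes out does not test what caused the difference in share.

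Next, the effects in the 2 tissues were tested against each other. The log2 effect was larger in liver than in brain for tiparp by 3.67 (SE 0.37), for ahrra by 5.89 and for CYP1B1 by 6.13. The DMSO livers held 3 reads of ahrra and 4 of CYP1B1, so the last 2 values rest on a baseline near the floor. CYP1B1 reached at most 19.31 CPM in PCB126 livers, below the mean of the PCB126 brains given above. Its larger ratio is thus not a higher level. It also differed for GRINA, a membrane protein linked to glutamate receptors (2.45, with log2 fold changes of 1.66 in liver and -0.79 in brain), and for LNX2, a ubiquitin ligase (2.3, with 1.73 and -0.54). It was lower in liver for CCDC28B (-4.97). These were the 6 of 21503 genes past edgeR's interaction test with Benjamini-Hochberg adjustment, with adjusted p between 0.00126 for tiparp and 0.0183 for CCDC28B (3069 at an unadjusted p under 0.05). With the fish as a block 1 passed, tiparp (3.58). Next in order among lower effects were sycp2 (-7.04), htr1aa (-3.96), emilin1b (-2.13) and RPP14 (-1.14), not past the test (0.0559 to 0.0790). The count was 61 without DMSO replicate 2, 3 without DMSO replicate 4, 3 without PCB126 replicate 1 and 10 without the brain of PCB126 replicate 1 alone. DESeq2 called 608, and DESeq2's size factors in the edgeR test gave 11. Calls ended for LNX2 without DMSO replicate 4 (0.0721) or PCB126 replicate 1 (0.0598), for CYP1B1 without DMSO replicate 4 (0.0522) or PCB126 replicate 1, 2 or 4 (0.0641, 0.0556, 0.0566), and for CCDC28B without DMSO replicate 3 or 4 (0.114, 0.0632) or any 1 of the PCB126 replicates (0.0644, 0.0982, 0.0901, 0.0566).

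Genes called in both tissues were CYP1A1, CYP1B1, cyp1c1, ahrra and ENSDARG00000097714, all higher in both. Among 14812 genes tested in both tissues, 6 were called in liver and 2577 in brain, with an overlap of 5 where independent lists give 1.04 (Fisher's exact test, p = 8.15e-04). At an unadjusted p under 0.05 the overlap was 512 genes, where independent lists give 522 (exact p = 0.552), and 400 of them (78.1%) had the same sign in both tissues. The tissues come from the same fish, so a check added after the data were seen took all 35 divisions of the 8 fish into 4 and 4. Of these, 21, the real one included, gave at least that percentage (25% to 100% in the others). The overlap in the others was 9 to 378 genes, so their percentages rest on fewer genes than the 512 of the real one. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.150 and a Spearman correlation of 0.219. With a fish left out of both tissues the overlap was 1 without DMSO replicate 1, 1 without DMSO replicate 2, 2 without DMSO replicate 3, 2 without DMSO replicate 4, 2 without PCB126 replicate 2 and 3 without PCB126 replicate 3. The Pearson correlation was 0.302 without DMSO replicate 2, 0.0877 without DMSO replicate 3 and 0.0621 without PCB126 replicate 2.

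Mean methylation did not differ between treatments past the test. Over 451572 cytosines shared by the livers, the mean level was 58.6 ± 0.193% in DMSO and 58.7 ± 0.183% in PCB126 fish (SD, n = 4), a difference of 0.0388 points (exact permutation test, two-sided, p = 0.800). Over 358445 cytosines shared by the brains it was 50.3 ± 0.275% and 50.4 ± 0.498%, a difference of 0.180 points (exact permutation p = 0.600). The sign of the difference turned without liver DMSO replicate 2 (-0.0351) or PCB126 replicate 3 (-0.0356), and without brain PCB126 replicate 1 (-0.0464).

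**Figure D4:**
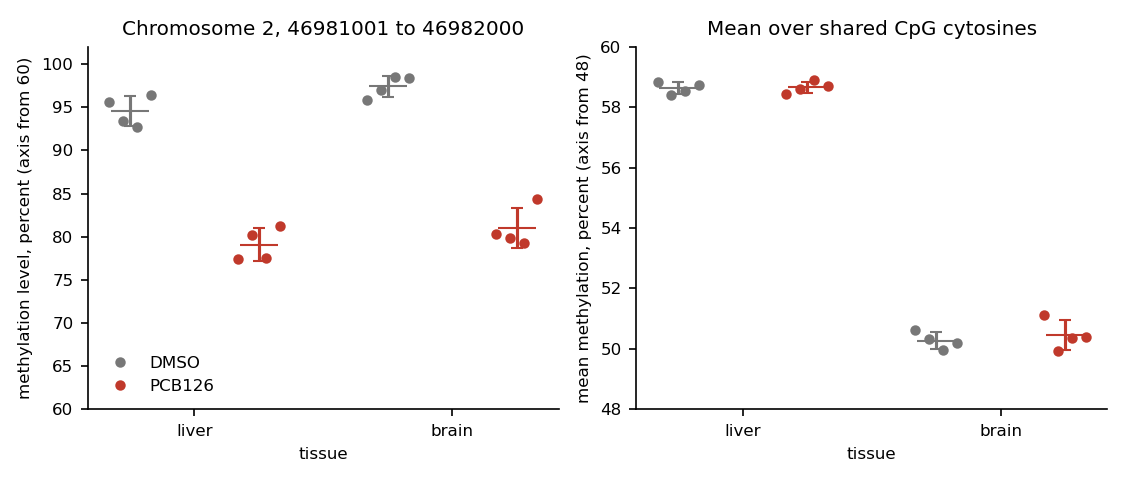
Methylation level (percent) per fish in the window from 46981001 to 46982000 on chromosome 2 and mean level over shared CpG cytosines, in liver and brain of DMSO and PCB126 fish, with points for fish and bars for mean ± SD. In the window the PCB126 means were 79.1% in liver and 81.0% in brain, against 94.6% and 97.4% in DMSO fish.

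At single windows, a region on chromosome 2 (46981001 to 46982000, GRCz10) was lower with PCB126 in both tissues. Liver and brain came from the same 8 fish, so the second tissue is not an independent repeat. In a check added after the data were seen, 7 of the 35 divisions of these fish into 4 and 4 called at least 1 window in both tissues, the real one (1 window) included, with a highest of 3. The level of this region was 94.6 ± 1.77% in DMSO and 79.1 ± 1.91% in PCB126 livers, and 97.4 ± 1.25% and 81.0 ± 2.32% in brains (SD, n = 4), from 133 or more reads over 7 to 8 cytosines per library. The difference was -15.5 points in liver (quasi-binomial test with Benjamini-Hochberg adjustment, adjusted p 0.0484) and -16.5 points in brain (0.0215). Over the 7 cytosines shared by all libraries of a tissue, a choice made after the data were seen, it was -16.2 (0.0306) and -16.7 (0.0245). The call ended in liver in each of the 8 leave-outs (adjusted p 0.0569 without PCB126 replicate 4 to 0.152 without PCB126 replicate 2; DMSO replicates 0.101, 0.103, 0.109 and 0.135; PCB126 replicates 1 and 3 0.113 and 0.0670). In brain it ended without DMSO replicate 3 (0.0515) and without PCB126 replicate 1, 2 or 3 (0.104, 0.113, 0.102).

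In liver 3 of 107847 windows were called (7616 at an unadjusted p under 0.05). A second window on chromosome 2 (35277001 to 35278000) had 82.0 ± 1.43% in DMSO and 51.2 ± 3.81% in PCB126 livers (n = 4), a difference of -30.7 points (adjusted p 2.79e-04), from 259 or more reads per library. Over 12 shared cytosines it was -21.7 points (adjusted p 0.0621), and in brain the window differed by -16.9 points (unadjusted p 6.52e-05), or by -11.0 points over shared cytosines, and was not called. The third, on chromosome 12 (5324001 to 5325000), was higher by 30.8 points with overlapping groups, held no cytosine shared by all 8 livers, and is named after its value was seen. It lost its call in 6 leave-outs, those of DMSO replicates 1, 3 and 4 (adjusted p 0.0930, 0.109, 0.102) and PCB126 replicates 1, 2 and 3 (0.113, 0.763, 0.0501), and the second window in none. The liver count was 5 without DMSO replicate 1, 5 without DMSO replicate 2, 1 without DMSO replicate 3, 1 without PCB126 replicate 1, 1 without PCB126 replicate 2 and 7 without PCB126 replicate 4. A logistic model without a spread between fish called 390 windows, and limma on M values 0.

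In brain 8 of 91618 windows were called, 1 higher and 7 lower (6040 at an unadjusted p under 0.05). Beside the window on chromosome 2, the largest differences were -79.7 points on chromosome 6 (52472001 to 52473000), -61.8 on chromosome 21 (7712001 to 7713000), -59.8 on chromosome 23 (8687001 to 8688000), -57.8 on chromosome 10 (22635001 to 22636000) and -53.9 on chromosome 23 (18212001 to 18213000). On chromosome 2 (44692001 to 44693000) the level was higher by 46.3 points. In the 5 windows with these decreases each PCB126 library stood at 0%, and single libraries listed from 1 to 18 cytosines per window. Over the cytosines shared by all 8 brains the differences were 0.00 to -1.39 points, and 2.13 points in the higher window, and 2 windows were called in brain in all. Except for the window on chromosome 6, these windows lost their call without any 1 of the PCB126 replicates (adjusted p 0.0887 to 0.265). Without DMSO replicate 3 the calls on chromosomes 23 and 10 and of the higher window ended (0.0515 to 0.0561). Without DMSO replicate 1 or 4 those at 22635001 and 18212001 ended (0.0566 to 0.0598), and without DMSO replicate 2 that at 22635001 (0.0611). The count with all cytosines was 3 without DMSO replicate 3, 2 without PCB126 replicate 1, 1 without PCB126 replicate 2 and 1 without PCB126 replicate 3.

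As a yardstick, liver and brain of DMSO fish were compared in the same way. Of 138457 windows, 26972 differed, 20151 higher and 6821 lower in liver, and the groups did not overlap in 24817 of them (27074 windows with the fish as a block). The largest difference upwards was on chromosome 19 (12256001 to 12257000), with 98.9 ± 2.17% in liver and 8.03 ± 2.48% in brain (SD, n = 4; quasi-binomial test, adjusted p 9.4e-07), and downwards on chromosome 15 (16068001 to 16069000), with 13.2 ± 12% and 98.9 ± 2.27% (3.48e-05). The smallest read number of a library in these windows was 11. Window levels here rest on each library's own listed cytosines, and a count over shared cytosines is not given. Liver DMSO libraries listed 886120 to 1530194 cytosines and brain DMSO libraries 1449650 to 1942803. Different cytosines could therefore account for part of the count.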

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

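The tests of carried-over tissue, neuron share, handling, vitellogenin and of windows called without a spread between fish were chosen only after the result was seen. Of 247 groups of 4 libraries, 25 (10.1%) held a library far from the other 3, where chance gives about 1 in 20, and 9 of the 25 fell on brain PCB126 replicate 1. In addition, 6 genes differed in effect between the tissues by the interaction test.

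The first pattern is the broad shift of expression in brain, where 2958 genes were called while no other division of the 8 fish called any by edgeR (at an unadjusted p under 0.05, 7483 genes against at most 3225). Muscle markers took 5.738% of reads in brain PCB126 replicate 1, next to 0.1683% in the second highest of the group. Without that library 3774 genes were called, which argues against tissue carried over in that library as the whole cause. Without both PCB126 replicates 1 and 3, the 2 brains highest in muscle reads, 2452 genes were called, 1795 of them also with all fish. Tissue carried over in the remaining brains was not tested. The rod opsin rho lay at 42.0 and 39.4 CPM in PCB126 replicates 2 and 3, and gh1 at 57.1 and 52.6 CPM in DMSO replicates 1 and 2. A lower share of neurons alone would raise the markers of all other brain cell types. Of 57 tested, 4 were lower past the test (KDR, SLC2A1_01437 and flt1 of endothelium, and mag) and 2 were higher (AQP1_23713 and FABP7_07697). Log2 fold changes were positive in 13 of 18 microglia and macrophage markers and 6 of 14 of astroglia. They were positive in 5 of 15 of endothelium and 5 of 10 of myelin. With such mixed signs the markers do not decide on the share of neurons. A difference in handling or RNA preparation between the groups may remain: each PCB126 brain had a mitochondrial share at least 2.24 percentage points above each DMSO brain, and handling and exposure cannot be told apart here because no label separates them. An effect of PCB126 on the brain stays open as well.

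The second pattern is the vitellogenin level of single livers, 41.74% of reads in genes in DMSO replicate 2 against 0.02017% in the next DMSO liver. The highest DMSO share lay 41.74 percentage points above the lowest PCB126 share, which argues against PCB126 as the only cause. Carried-over ovary or eggs as the only source of both would keep vitellogenin and the egg-coat gene zp3a.1 in 1 ratio. The ratio varied 49-fold among the 4 livers with over 1% vitellogenin. This cannot tell whether ovary was present in addition to vitellogenin made in liver. The groups may each hold females and males: the division that sets DMSO replicate 2 and PCB126 replicates 1, 2 and 4 against the rest called 341 liver genes and 57 liver windows, with 17 windows as the next highest, but 1 window in brain, where the division by treatment called 8. This points to a structure of the samples other than treatment, and sex cannot be told apart from other differences between these fish because the labels used here do not give it.

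The third pattern is the number of windows called by the logistic model that ignores the spread between fish, 390 in liver and 526 in brain. Of the 390, 292 held cytosines shared by all 8 livers and 213 were called over these too, with a median difference of 30.6 points against 30 over all cytosines, which argues against different cytosines as the whole cause there. In brain 153 of the 526 were called over shared cytosines too, and over the 398 that held such cytosines the median fell from 30.9 to 16.7 points, so different cytosines could account for part. Levels that differ from fish to fish, by genotype for example, are a candidate explanation in both tissues. Over all cytosines, 20 of the 35 divisions of the livers gave as many windows (real 390, others 302 to 521). In brain only the real one did (526, others 250 to 384), a division that also separates the libraries by depth. Over shared cytosines, 11 of the 35 divisions of the livers gave as many windows (real 389, others 278 to 471) and 14 of those of the brains (real 298, others 226 to 352). These windows showed the same sign in the other tissue of the same fish in 94.1% of cases for liver and 95% for brain, and in 85.8 to 98.5% and 93.8 to 98.7% under the other divisions.

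The following libraries stood far from the other 3 of their group, and no explanation was tested for them. In liver, 53.94% of reads in DMSO replicate 2 mapped to more than 1 place, and PCB126 replicate 2 had 91125645 reads over listed cytosines, against 26933389 in the next of its group. CYP1B1 lay at 19.31 CPM in liver PCB126 replicate 3, and bmal2 at 7.614 CPM in liver DMSO replicate 2. Brain PCB126 replicate 1 was highest in ADM_69027 (34.5 CPM), UROC1 (36.61), prss59.2 (44.78), HSP90AB1 (1404), flt1 (17.37) and KDR (5.29 CPM), and lowest in AHCYL1 (99.66) and PCSK2 (22.06 CPM). Brain DMSO replicate 4 was lowest in cyp1c1 (1.161 CPM) and highest in PTGES3_37284 (169.2), fth1a (1188) and AHCYL1 (205.5 CPM). Brain DMSO replicate 1 was highest in igfn1.2 (6.498 CPM), OCIAD2 (65.25) and MTHFD1L (15.07 CPM). DGAT1_54914 was lowest in brain DMSO replicate 2 (13.59 CPM), il1b highest in brain PCB126 replicate 3 (17.43 CPM), and in brain DMSO replicate 3 ELAVL3 was lowest (304.0 CPM) and HPD highest (2.057 CPM).

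The effect in liver minus that in brain was 3.673 on the log2 scale for tiparp, 2.449 for GRINA, 5.891 for ahrra, 2.301 for LNX2, 6.126 for CYP1B1 and -4.965 for CCDC28B.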

How the results depend on the processing

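The alternatives with the vitellogenin covariate, egg genes or mitochondrial genes left out, PCB126 replicates 1 and 3 left out together, the brain of PCB126 replicate 1 left out alone, a fish left out of both tissues in the shared effects, and cytosines shared by all 8 libraries were chosen after the data were seen. Of the summary results under an alternative, 87 stayed within 1.5 times or 1 SD of the reported value or on its side of the threshold, 71 moved further and 5 changed sign. Liver gene counts of 7 became 364 by DESeq2, 150 by voom, 231 with all 16 libraries in 1 fit and 32 with the vitellogenin covariate. Brain counts of 2958 became 5585 by DESeq2, 5336 by voom, 1827 with no filter, 10 with all 16 libraries and 489 at an absolute log2 fold change of at least 1. The interaction count of 6 became 11 with DESeq2's size factors, 608 by DESeq2 and 10 without the brain of PCB126 replicate 1. Called lists fell from 16 to 1 in liver and from 8 to 0 in brain with an estimated correlation, and to 4 and 1 by fry. The overlap of the tissues was 512 at an unadjusted p under 0.05. For most of these the cause was not tested; the fold minimum and the window difference keep fewer by construction.

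Window counts of 3 in liver and 8 in brain became 1 and 13 at a coverage minimum of 20, 15 and 15 at single CpGs, 390 and 526 without overdispersion, 0 (5013 at an unadjusted p under 0.05) and 18 by limma on M values, and 389 and 298 over shared cytosines without overdispersion. In liver the count was 1 with windows of 500 bp and 5 with at least 3 libraries per group, and in brain 2 over shared cytosines. Liver against brain, 15683 windows differed by at least 25 points. The mean methylation difference in liver turned from 0.0388 to -0.0217 points at a coverage minimum of 20 and to -0.120 with pooled reads; the cause was not tested.

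Leaving out 1 library at a time gave 2 to 50 genes in liver, 3 to 4464 in brain, 16 to 18 lists in liver and 6 to 14 in brain, and 1 to 7 windows in liver and 1 to 12 in brain. Leaving out 1 fish, with both its tissues, gave 3 to 61 genes for the interaction, 24137 to 29631 windows between the tissues, an overlap of 1 to 5 and a correlation of fold changes of 0.0621 to 0.302. With 1 library left out, mean methylation differences ranged from -0.0356 to 0.110 points in liver, including -0.0351 without DMSO replicate 2, and from -0.0464 to 0.353 in brain. The log2 fold change of brain tiparp ranged from -0.0888 to 0.00330, the latter without PCB126 replicate 2, around -0.04 with all fish. For the genes named in liver and in the interaction, 338 values stayed on their side of the threshold, 24 fell short of it and 36 moved past it. For those named in brain the counts were 930, 752 and 2. The cause was not tested.

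With the replicate number as a block, 4 genes were called in liver and 1 in brain, 17 and 13 lists, and 0 windows in either tissue by the quasi-binomial test (5832 and 6291 at an unadjusted p under 0.05). Sign flips within these pairs gave exact p of 1 and 0.5 for the mean methylation differences, where 0.125 is the smallest possible. With the fish as a block the interaction called 1 gene. Equal numbers of DMSO and PCB126 fish did not clearly pair. Their deviations correlated at -0.0694 to 0.428 in liver RNA, 0.0528 to 0.126 in brain RNA and -0.0276 to 0.0540 in methylation. Not every library correlated best with its own number. In brain RNA unequal numbers gave -0.127 to 0.0803, so a structure by replicate number is not excluded there. Between the tissues, the fish as a block gave 27074 windows. Depth differed along the groups in brain, where PCB126 libraries listed 587981 to 908136 cytosines and DMSO libraries 1449650 to 1942803. On data simulated with a preset spread, the window test called 3% of windows changed by 30 points in brain and 17% in liver. The median was 132 and 118 reads per tested window, and the part of depth in this was not tested. Not run were a coverage minimum of 5, since the files start at 10, and all alternatives of the comparison of changed genes with changed windows, which was not made.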

Other observations

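The divisions over shared cytosines and the grouping of divisions between tissues by fish were tested only after the result was seen. Beyond the lists given above, single genes of energy metabolism moved in brain by edgeR's quasi-likelihood test. Of 29 genes of glucose metabolism 3 rose and 1 fell (8 and 2 when adjusted over the list alone), with gains of 0.62 in the lactate dehydrogenase LDHA, 1.72 in the glycogen phosphorylase PYGL and 1.74 in igfbp1b, and a loss in PFKFB3 (-0.62). The electron transfer genes ETFA (0.75) and ETFB (0.67) rose and CPT2 (-0.50), which carries fatty acids into mitochondria, fell. Camera's adjusted p was 0.255 for glucose metabolism and 0.787 for fatty acid oxidation. The share of called members in these lists was not above that over all brain genes (2958 of 20096). The hormone receptor NR3C2 fell by 0.60 on the log2 scale while THRB (0.50) and SRD5A2_43587 (1.51) rose (camera 0.690 for the list). The neuropeptide gene VIP rose by 0.97 (0.0518), the cytokine gene il1b by 1.92 with crp1 at -0.68 (acute phase list 0.0518), and the keratins krt18b and krt18a.1 by 1.98 and 0.91 (0.490). Among markers of other cells RHAG rose by 2.06, HPD by 1.5 and SYCP1 by 1.99, and PCSK2 fell by 0.76. PYGL (18.3 CPM) and krt18b (146 CPM) were highest in PCB126 replicate 1, the library with muscle reads. As for the other brain genes, 2 of the 92 that the naming rule gave as past the test passed without DMSO replicate 1, and likewise 2 without DMSO replicate 2, DMSO replicate 3 or PCB126 replicate 2.

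Brain libraries differed in markers of structures next to the brain, and the genes named for them were chosen after their values were seen. The pituitary list had a median log2 fold change of -3.26 over 6 genes (0 past the test over all genes, 3 lower when adjusted over the list alone; camera adjusted p 0.157). Growth hormone gh1 lay at 57.1 and 52.6 CPM in DMSO replicates 1 and 2, and at most at 11.7 CPM in the other 6 brains. The rod opsin rho lay at 42.0 and 39.4 CPM in PCB126 replicates 2 and 3 and at most at 1.28 CPM elsewhere, and the retina list had a median of 1.07 (4 higher when adjusted over the list alone; 0.424). The lists not called had medians from -1.43 to 1.07 in liver (smallest camera adjusted p 0.0643) and from -3.26 to 2.92 in brain (0.0518). In liver the ovary list had a median of -1.43 while camera gave it the direction up (0.141), and in brain AHR partners had a median of 0.01 and a mean of -0.02.

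Each test of treatment across genes or windows was repeated on all 35 divisions of the 8 fish into 4 and 4, the real one included. For the count of brain genes only the real division was as large (real 2958, highest other 0 by edgeR). At an unadjusted p under 0.05 it was 7483 against at most 3225. That is the smallest share that 35 divisions can give, so chance is unlikely there but not excluded. The brain count at the adjusted threshold was also unstable, at 3 to 7 without DMSO replicate 1, 2 or 3 or PCB126 replicate 2, and 1 with the replicate block. At an unadjusted p under 0.05 these leave-outs gave 5700 to 6845 genes and the block 6195. Other divisions were as large for the count of liver genes (2 divisions, real 7 and highest other 341) and the interaction (2, with 6 against 62). So they were for the liver lists (7, with 16 against 20) and the brain lists (31, with 8 against 22), and chance was not excluded for these 4 results. Nor was chance excluded for the correlation of the tissues (14, with 0.150 against 0.346) or the liver windows (13, with 3 against 57). In liver and in the interaction, the division with the highest count is the one described with vitellogenin. Of the 7 liver genes called by treatment, 0 were called in any other division. All 7 had values without overlap between the treatment groups, and each other division mixes these groups, so it could hardly call them. The divisions therefore concern the count of liver genes and do not test these genes singly.

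For the brain windows 1 division was as large (real 8, highest other 7), a margin of 1 window in a division that also separates the libraries by depth. Over shared cytosines the called windows other than that on chromosome 2 at 46981001 differed by at most 2.13 points, 12 divisions gave at least the 2 windows of the real one, with a highest of 9, and the replicate block gave 0. The count with all cytosines is therefore not used here to exclude chance. For the windows between tissues, the divisions are of the 8 DMSO libraries, a liver and a brain from each of 4 fish. Of the 35, 8 separate liver from brain in every fish, which is too few for a share under 0.05 (1 division as large; real 26972, highest other 0). Of the others, 24 keep both tissues together in 2 of the fish and called 0 windows, and 3 keep them together in all 4 and called up to 158.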
